A study of Homo sapiens with 2 samples.

How the data were processed

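RNA m5C was profiled in HepG2 cells of 2 groups, sh-NC and sh-NSUN6, with 1 library each. Per the labels' protocols, hairpins in a lentiviral vector were packaged in HEK293T cells, a human embryonic kidney line used to make virus, and stable HepG2 lines were grown to about 80% confluency. Per the labels' protocols, RNA extracted with TRIzol was treated with DNase, enriched for polyadenylated transcripts and broken with 20 mM zinc chloride into fragments of about 200 nucleotides. It was then mixed with a 28S rRNA negative control, treated with bisulfite and reverse transcribed from random primers. Bisulfite turns unmethylated cytosine into uracil, so a cytosine that escapes conversion reads as methylated, and the 28S control is the kind of material that measures such escape. No conversion rate is given in the sources used here. The labels call the control's genotype wild type while its title names the sh-NC hairpin, and the title was used for its group.

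The authors' deposited tables hold methylation levels in percent, from 0 to 100, 1 gene per line. Per the file headers there are 28 columns of values, for CG, CHG, CHH and all cytosines in 7 regions (promoter, 5' UTR, exon, intron, 3' UTR, gene body and downstream). The aligner, the methylation caller, the genome build, the gene annotation, any coverage minimum and the use of the 28S control are not given in the sources used here. Whether the authors pooled calls over a region or averaged site levels is likewise not given. The tables carry no counts and no coverage, so depth and precision per gene are unknown. A value of 0 can stand for covered cytosines without a methylated call or for no covered cytosine, which is why folds were computed only where both libraries were above 0. Levels of genes covered by few reads can lie near 0 or near 100 by chance, and a fold between small percentages is sensitive to this.

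The main measure was the level over all cytosines of the gene body. For each library the median and quartiles over genes above 0 were computed. For genes above 0 in both libraries the log2 ratio of sh-NSUN6 over sh-NC was computed with no pseudocount, and a difference of 2-fold or more was counted. The design foresaw Fisher's exact test on methylated and unmethylated calls with at least 30 calls per gene; without calls in the tables the rule for levels, also fixed in advance, was used, and no p-value was computed. Gene lists (26 lists, 719 entries) were matched by symbol and by older symbols, which found 17 tRNA synthetase, 15 histone and 8 oxidative phosphorylation genes, 1 m6A gene and 1 interferon gene. For the 25 lists with at least 5 members above 0 in both libraries, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on decile of the mean level. This percentile describes these libraries and is not a test of the conditions.

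The genes named by rule were the 10 largest increases and 10 largest decreases in percentage points among the 2-fold genes, NSUN6 and the members of the m5C list, the 3 members of each other list with the highest mean level, and for each library the 5 genes with the highest level that were at 0 or not listed in the other. APOM and the genes named in the closing observations on high levels and markers were chosen after their values were seen. Y-linked genes and XIST were left out of the named genes, and some other genes that the rule takes are not reported here. Of 16528 names in either table, 14452 matched a symbol of GENCODE version 44. Coordinates in the text are those of the gene with the same symbol in that annotation, on GRCh38; the tables carry no coordinates and name no build, and genes listed under older symbols, such as WISP1, ACPP, H1F0 and WARS, had no such match. The 3' UTR sequences for a motif test came from the canonical transcripts of the same annotation.

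Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The 2-fold rule was tested on simulated data made from the 13739 genes with 200 of them changed. It recovered 52.0% of genes changed 2-fold, 90.5% of those changed 3-fold and 94.0% of those changed 4-fold. It called about 9.5% of the unchanged genes, since the simulation kept the spread between these libraries. The share recovered at 2-fold, which is the threshold itself, and the share of unchanged genes called were thus largely fixed by construction. In simulated lists of 30 genes the percentile lay outside the range in 5% of unchanged lists and in 100% of lists shifted by 0.5 on the log2 scale. The largest list median in the data was 0.29 in size, and shifts that small were not simulated.

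Alternatives fixed in advance were other fold thresholds (1.5-fold and 4-fold), a pseudocount of 1.76 (the 10th percentile of nonzero levels) with genes at 0 or not listed in 1 table kept, centring on the median ratio, a minimum level, percentiles of the difference, the mean in place of the median, and random lists without matching. Other regions, the CHH context, agreement of all 3 contexts and genes under 20% alone were added after the data were seen. With no replicate error, a value was taken to have moved when it changed by more than 1.5-fold, or a median log2 ratio by more than 0.1. Minimums of 10 and 100 calls and weighting by coverage were not run, because they need coverage. Promoter and downstream levels were not part of the comparisons.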

Results

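RNA cytosine methylation (m5C) was measured by bisulfite sequencing in HepG2 cells, a human line derived from a liver tumour, that carried either a control short hairpin RNA (sh-NC) or a hairpin against NSUN6 (sh-NSUN6). NSUN6 is a methyltransferase that places m5C on tRNAs and on a set of mRNAs. Each group had 1 library, so no difference between the groups has a replicate check, and every comparison given here is between these 2 libraries. The tables gave a methylation level per gene, as a percentage, and no read counts, so the depth behind each value is unknown and no interval can be attached to it. The sh-NC table listed 15484 genes, of which 13959 had a level above 0 over the gene body. The sh-NSUN6 table listed 16208 genes, of which 14458 had such a level. In total 16528 genes were listed, 15164 of them in both tables, and 13739 genes were above 0 over the gene body in both. A further 220 genes were above 0 in sh-NC alone and 719 in sh-NSUN6 alone, a ratio of 3.27.

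The first question was the state of the targeted gene. Transcripts of NSUN6 (chromosome 10, 18545561 to 18659285, minus strand, GRCh38) had a gene-body level of 3.35% in sh-NC and 3.84% in sh-NSUN6, a log2 ratio of 0.20. Within the gene, the 3' UTR level was 8.38% in sh-NC and 2.16% in sh-NSUN6, and the 5' UTR level was 1.18% and 7.78%. The exon level was 1.11% and 2.22%, and the intron level was 5.28% and 4.53%. A methylation level is not a measure of abundance, so these values do not check the knockdown.

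The series asked how m5C levels differed between the knockdown and the control. Over all genes the levels of the libraries lay close together. Unconverted cytosines count toward these levels and no conversion rate is given, so this closeness does not show that m5C was unchanged. The median gene-body level was 3.09% in sh-NC (middle 50% of genes from 2.31% to 4.26%) and 3.10% in sh-NSUN6 (2.36% to 4.17%). The mean of the gene levels was higher in sh-NC, at 4.68% against 4.57%. The median ratio of sh-NSUN6 over sh-NC among the 13739 genes above 0 in both was 0.012 on the log2 scale, and the middle 50% of genes lay between -0.29 and 0.31. Of these genes 51.0% were higher in sh-NSUN6, 48.4% were lower and 0.531% were equal. Among the genes at or above the median mean level, the median ratio had the opposite sign, at -0.027. The log2 levels of the libraries had a Pearson correlation of 0.72, and the levels a Spearman correlation of 0.63, across genes, which are not independent replicates.

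Gene regions and sequence contexts gave the same picture of small median differences. In 3' UTRs, where levels above 0 in both libraries were found for 10636 genes, the median level was 2.59% in sh-NC and 2.66% in sh-NSUN6, with a median log2 ratio of 0.041. In exons of 12780 genes the medians were 2.64% and 2.67%, in introns of 9962 genes 2.74% and 2.83%, and in 5' UTRs of 10972 genes 3.27% and 3.29%. Cytosines followed by guanine (CG) had a higher median gene-body level than those in the CHH context, where H is any base but guanine. The CG medians were 3.67% in sh-NC and 3.74% in sh-NSUN6, the CHG medians were 3.51% and 3.55%, and the CHH medians were 2.79% and 2.80%.

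**Figure D1:**
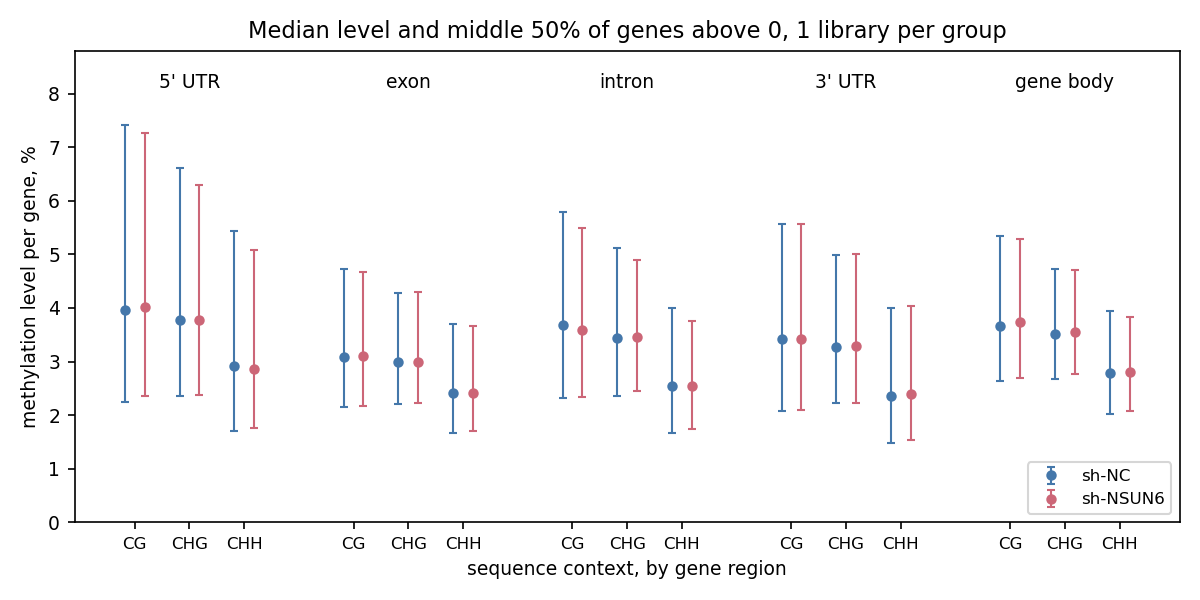
Methylation level per gene in percent (vertical axis) by sequence context and gene region (horizontal axis) in the sh-NC library (blue) and the sh-NSUN6 library (red), 1 library per group. Points are medians over genes above 0 in that library and bars span the middle 50% of genes, which overlap in each pair; for 3' UTR CHH cytosines the medians were 2.36% and 2.40%.

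Single genes differed in both directions. A level at least 2-fold apart was found in 1321 genes, or 9.61% of those above 0 in both libraries, with 691 higher and 630 lower in sh-NSUN6. When genes at 0 or without a row in 1 table were kept, with 1.76 percentage points added to each level, 705 genes were higher and 383 lower, so the higher share moved from 52.3% to 64.8%. Most of the 1321 genes had low levels, with 1213 under 20% in both libraries. A level in each of the 3 sequence contexts was available for 936 of the 2-fold genes. Of these, 862 differed in the same direction in all 3 contexts, and 343 did so by 2-fold or more in each, 167 higher and 176 lower. Among all 12872 genes with levels in the 3 contexts, 56.6% had the same direction in each. Picking genes by the level of all cytosines, which the 3 contexts make up, raises this agreement by construction. The share of genes with a 2-fold difference was 12.7% in exons, 23.7% in 5' UTRs, 23.9% in introns and 24.1% in 3' UTRs.

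Several of the genes with the largest differences were near 100% in sh-NC and lower in sh-NSUN6. NFATC1, a transcription factor activated by calcineurin (chromosome 18, 79395856 to 79529325), was at 100% in sh-NC and 0.890% in sh-NSUN6. Its sh-NC level came from the 5' UTR and its sh-NSUN6 level from exons. ADAMTS2, a procollagen-processing protease (chromosome 5, 179110853 to 179345461), was at 97.2% from exons in sh-NC and at 9.61% from introns in sh-NSUN6. RCSD1 was at 100% and 14.7%, CDC42EP5 at 94.4% and 14.1%, WISP1 at 73.5% and 3.66%, and NRIP3 at 87.7% and 21.7%. TNFAIP6, which encodes a secreted hyaluronan-binding protein, was at 75.5% and 9.48%. HAS1, a hyaluronan synthase gene, was at 100% and 17.97% over the gene body, and its 3' UTR was at 100% and 99.3%. TNFRSF11B, which encodes the decoy receptor osteoprotegerin, was at 99.5% and 45.0% over the gene body. Its exons were at 99.5% and 100%, near the top of the scale in both libraries, so the decrease was not seen there.

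Among genes higher in sh-NSUN6, APOL3 (chromosome 22, 36140329 to 36166177) was at 16.0% in sh-NC and 99.2% in sh-NSUN6. THY1, which encodes a surface glycoprotein of fibroblasts and other cells (chromosome 11, 119415476 to 119424985), was at 1.01% and 82.0%, with its levels in the 3' UTR. CETP, the plasma cholesteryl ester transfer protein gene, was at 1.30% and 66.7%, with its levels in introns. The laminin gene LAMA4 was at 34.3% and 84.2%, the pregnancy glycoprotein gene PSG5 at 13.6% and 65.0%, and the actin-bundling gene ESPN at 11.5% and 61.3%. The glypican gene GPC6 was at 1.19% and 46.2%, where its exons were at 0 and 96.1% and its introns at 1.19% and 1.62%. The remaining 3 of the 10 largest increases were protocadherin gamma genes, PCDHGA10, PCDHGB1 and PCDHGA12, all at 78.3% in sh-NSUN6 and at 24.5%, 29.95% and 34.1% in sh-NC. PCDHGA12 stood for a tie of 12 genes of this cluster with the same pair of levels, whose transcripts share 3' exons, so the gene of origin of these reads is uncertain. Of the 20 genes, 19 had a level in at most 2 of 4 regions (5' UTR, exon, intron and 3' UTR) in at least 1 library, against 21.1% of all genes. A region with a level in both libraries existed for 18 of the 20, and 13 differed by 2-fold or more in the same direction in such a region. For a gene with a level in only 1 region, such as THY1, the region's ratio is the gene-body ratio. Its place among the 13 was then fixed in advance.

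**Figure D2:**
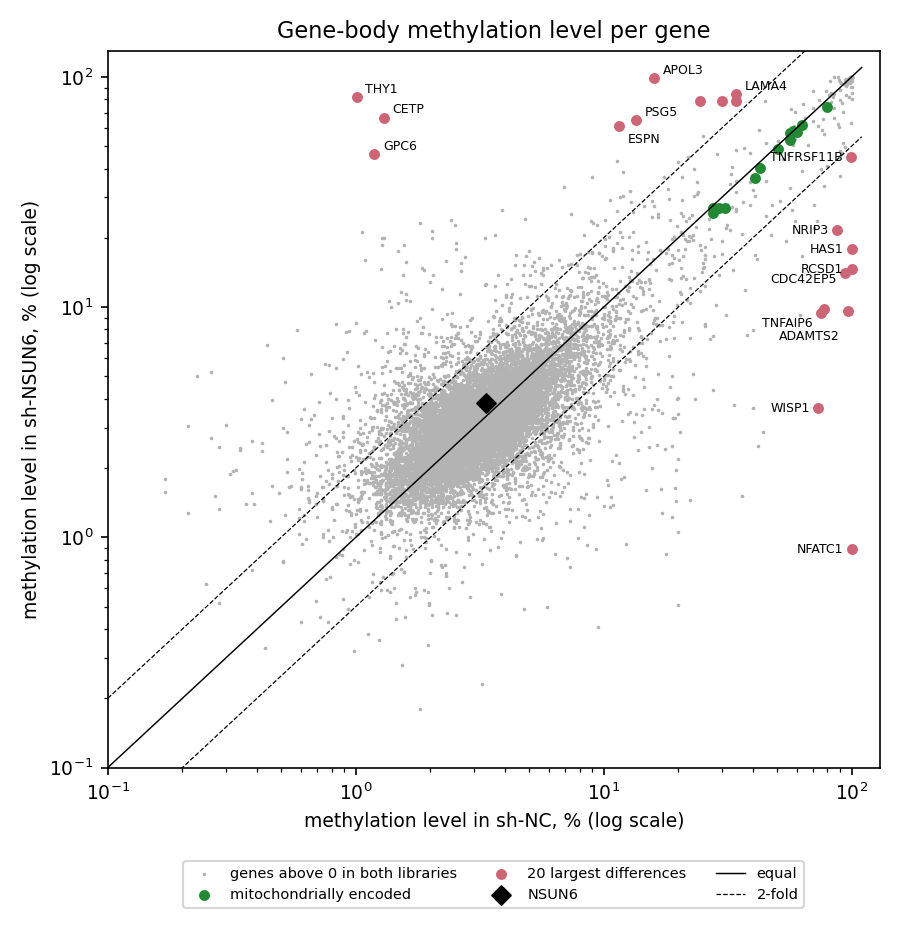
Gene-body methylation level in sh-NSUN6 (vertical axis, percent, log scale) against sh-NC (horizontal axis, percent, log scale), 1 library each. Each grey point is 1 of 13739 genes above 0 in both; the solid line marks equal levels and the dashed lines a 2-fold difference. The 20 largest differences (red, some unlabelled) lie outside the dashed lines, the 13 mitochondrially encoded genes (green) lie between them, and NSUN6 (black) was at 3.35% and 3.84%.

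Some genes had a high level in 1 library and no level in the other. The highest in sh-NC were ACPP and RP11-235D19.4 at 100%, CCBE1 at 99.6%, DLC1 at 99.4% and the early growth response gene EGR2 at 97.8%. In sh-NSUN6 8 genes were tied at 100%, among them CPXM2, the chemokine gene CXCL12, MXRA5, MYEF2 and RFX8. No fold is given for these genes because the other library had no level above 0.

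A list of m5C writers, erasers and readers, fixed before the data were examined, was measured in full. It was not limited to RNA m5C, as it also held the DNA methyltransferase genes DNMT1, DNMT3A and DNMT3B. Of 24 genes 11 were higher and 13 lower in sh-NSUN6, and 1 differed by 2-fold, with a median log2 ratio of -0.058 that lay at the 20.3rd percentile of 10000 random lists matched on level. NSUN7, a member of the NSUN family, was at 0.740% in sh-NC and 1.66% in sh-NSUN6, with its levels in introns. NSUN2, the main mRNA m5C writer, was at 3.41% and 2.59%, and the tRNA methyltransferase TRDMT1 at 1.38% and 2%. The m5C reader ALYREF, an mRNA export factor, was at 4.05% and 4.60%, and YBX1 at 3.31% and 3.00%. The m5C oxidase TET1 was at 5.49% and 3.54%, and TET2 at 2.81% and 3.05%. Among genes of the m6A pathway 5 of 21 were higher and 16 lower, with a median of -0.17 at the 5.99th percentile, and in exons a median of -0.012 at the 43.6th percentile. CBLL1, a component of the m6A writer complex, was at 6.52% and 2.68%, METTL14 at 5.14% and 4.32%, and ZC3H13 at 5.98% and 7.19%.

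None of the 25 gene lists with at least 5 measured members had a median outside the range of the middle 95% of matched random lists, where 1.25 lists are outside by chance. In exons 6 of the 25 medians had the opposite sign, those of m5C machinery, tRNA synthetases, glycolysis, lipid metabolism, cholesterol synthesis and cell cycle genes. Of the medians that kept their sign, 10 were smaller and 7 larger in exons by more than 1.5-fold, the highest percentile being that of iron and redox genes (91.4) and the lowest that of p53 targets (20.2). By the mean in place of the median, 1 list had the opposite sign, 6 were smaller and 6 larger by more than 1.5-fold. In the translation machinery, 22 of 33 small-subunit ribosomal protein genes were higher in sh-NSUN6 (median 0.20, 96.7th percentile). This list was outside the range, at the 97.7th percentile, when random lists were not matched on level, but its median was 0.012 at the 43.6th percentile in exons, and its mean was at the 81.3rd. Large-subunit genes were higher in 27 of 46 (0.093, 84.2nd percentile), translation factors in 23 of 35 (0.082, 83.6th percentile) and tRNA synthetases in 12 of 19 (0.079, 73.9th percentile). The members with the highest mean level did not all follow the median of their list. RPS29 was at 6.82% in sh-NC and 4.51% in sh-NSUN6, RPS2 at 5.89% and 4.08%, RPL34 at 7.71% and 5.44%, and EIF2S3 at 9.05% and 6.38%. EIF5B, a subunit-joining factor, was at 6.14% and 7.43%, and the tryptophanyl-tRNA synthetase gene WARS at 3.64% and 6.21%.

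In metabolism, glycolysis genes had the lowest percentile of the 25 lists. Of its 22 genes 14 were lower in sh-NSUN6, with a median of -0.19 at the 4.07th percentile, and this list was outside the range, at the 1.86th percentile, in the version with the added constant. In exons, however, its median was 0.025 at the 53.6th percentile, and by its mean it was at the 31.9th. The lactate dehydrogenase gene LDHA was at 6.64% and 5.19%, the phosphofructokinase gene PFKL at 9.31% and 8.21%, and HK2 at 5.84% and 5.11%. Lipid metabolism genes were higher in 14 of 23 (0.17, 92.1st percentile), with a mean of the opposite sign, -0.026. PLIN2, which coats lipid droplets, was at 98.8% and 93.7%, and the acyl-CoA synthetase gene ACSL1 at 16.6% and 5.13%. Cholesterol synthesis genes were higher in 15 of 25 (0.027, 43.98th percentile), where HMGCS1 was at 4.52% and 3.81% and CYP51A1 at 3.25% and 4.80%. Nuclear genes of oxidative phosphorylation were higher in 22 of 42 (0.016, 41.0th percentile), and the complex I gene NDUFS3 was at 6.46% and 2.79%. Iron and redox genes were higher in 13 of 22 (0.028, 59.96th percentile; 0.18 in exons), with ferritin heavy chain FTH1 at 6.59% and 8.84% and the superoxide dismutase gene SOD2 at 8.25% and 4.71%.

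Mitochondrially encoded genes had the highest median level of the 25 lists. The 13 genes above 0 in both libraries lay between 27.6% and 79.9% in sh-NC and between 25.6% and 74.2% in sh-NSUN6, 11 of them lower and 2 higher in sh-NSUN6, with a median log2 ratio of -0.089 at the 43.9th percentile. MT-ATP8 was at 79.9% and 74.2%, MT-ND4 at 62.9% and 61.6%, and MT-ATP6 at 60.5% and 57.7%. The other 24 of the 37 mitochondrial genes listed were at 0 in both libraries.

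In growth and stress pathways, cell cycle genes were higher in 22 of 38 (0.031, 56.2nd percentile), with the cyclin D1 gene CCND1 at 4.43% and 6.52% and E2F1 at 3.85% and 5.23%. DNA repair genes were higher in 15 of 25 (0.078, 68.8th percentile), where APEX1 was at 9.28% and 7.03%. Targets of p53 were lower in 14 of 20 (-0.16, 8th percentile; -0.087 in exons, and -0.27 by the mean at the 3.06th). MDM2, the ubiquitin ligase that limits p53, was at 7.26% and 3.36%, and the pro-apoptotic genes BBC3 and BAX were at 8.25% and 5.29%, and at 5.94% and 5.32%. Integrated stress and unfolded protein genes were lower in 13 of 25 (-0.030, 47.4th percentile), with the chaperone gene DNAJB9 at 6.36% and 12.1% and CALR at 10.6% and 7.61%. Heat shock genes were higher in 14 of 21 (0.11, 80.1st percentile), where HSPA1A was at 3.75% and 4.53%. Proteasome genes were lower in 20 of 30 (-0.10, 11.8th percentile), with PSMD14 at 5.82% and 8.03% and PSMC6 at 5.80% and 4.29%. Interferon response genes were higher in 20 of 31 (0.10, 88.5th percentile; 0.17 at the 96.97th with only genes under 20% in both libraries, and 0.20 by the mean at the 94.7th), although the antiviral gene MX1 was at 41.8% and 16.2%, and HLA-B was at 15.2% and 13.3%.

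Splicing and hnRNP genes were lower in 25 of 37 (-0.11, 11.4th percentile), where the splicing factor gene U2AF1 was at 9.26% and 3.88% and the helicase gene DDX5 at 10.5% and 7.42%. Histone genes were higher in 9 of 15 (0.13, 78.9th percentile), with the linker histone gene H1F0 at 9.83% and 16.7%. Cytoskeleton and adhesion genes were higher in 16 of 28 (0.045, 70.7th percentile), with the keratin gene KRT19 at 7.82% and 11.2% and TMSB10 at 6.91% and 9.79%. Wnt and liver cancer genes were lower in 11 of 20 (-0.054, 30.8th percentile). In that list the fetal growth factor gene IGF2 was at 99.1% and 63.2%, the midkine gene MDK at 58.3% and 50.7%, and the glypican gene GPC3 at 5.79% and 5.99%.

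Markers of liver and of other cell types were examined as lists of their own. Of 35 genes for proteins that hepatocytes secrete, 9 were listed in either table used here and 4 were above 0 in both, too few for a percentile, with 1 higher and 3 lower in sh-NSUN6. With the added constant, which kept 7 of the genes, the median was 0.37 at the 96.7th percentile, the opposite direction. The transferrin gene TF was at 7.84% and 6.62%, APOE at 3.75% and 2.75%, APOM at 2.55% and 2.29%, and VTN at 2.05% and 3.16%. The complement and coagulation list, also products of the liver in large part, had 19 of 33 genes listed and 16 measured, 9 higher and 6 lower (0.24, 95.4th percentile; 0.063 in exons, and 0.12 by its mean at the 73.2nd percentile), where C1R was at 5.67% and 9.71% and C1S at 10.1% and 9.05%. Among the 23 lists that describe neither liver products nor cells of other tissues, the median share of members listed was 100% and the lowest was 84%. Of 20 markers of stromal, endothelial and blood cells 11 were measured, 9 higher and 2 lower in sh-NSUN6 (0.29, 94.9th percentile). By its mean log2 ratio of 0.83 that list was at the 99.8th percentile, outside the range, and THY1 had the largest log2 ratio in it, 6.34. That gene weighs heavily in a mean of 11 genes, and the mean without it was not computed. In exons its median was 0.044 at the 56.7th percentile. The collagen gene COL1A2 was at 97.1% and 97.8% and the macrophage gene CD68 at 32.5% and 37.9%.

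**Figure D3:**
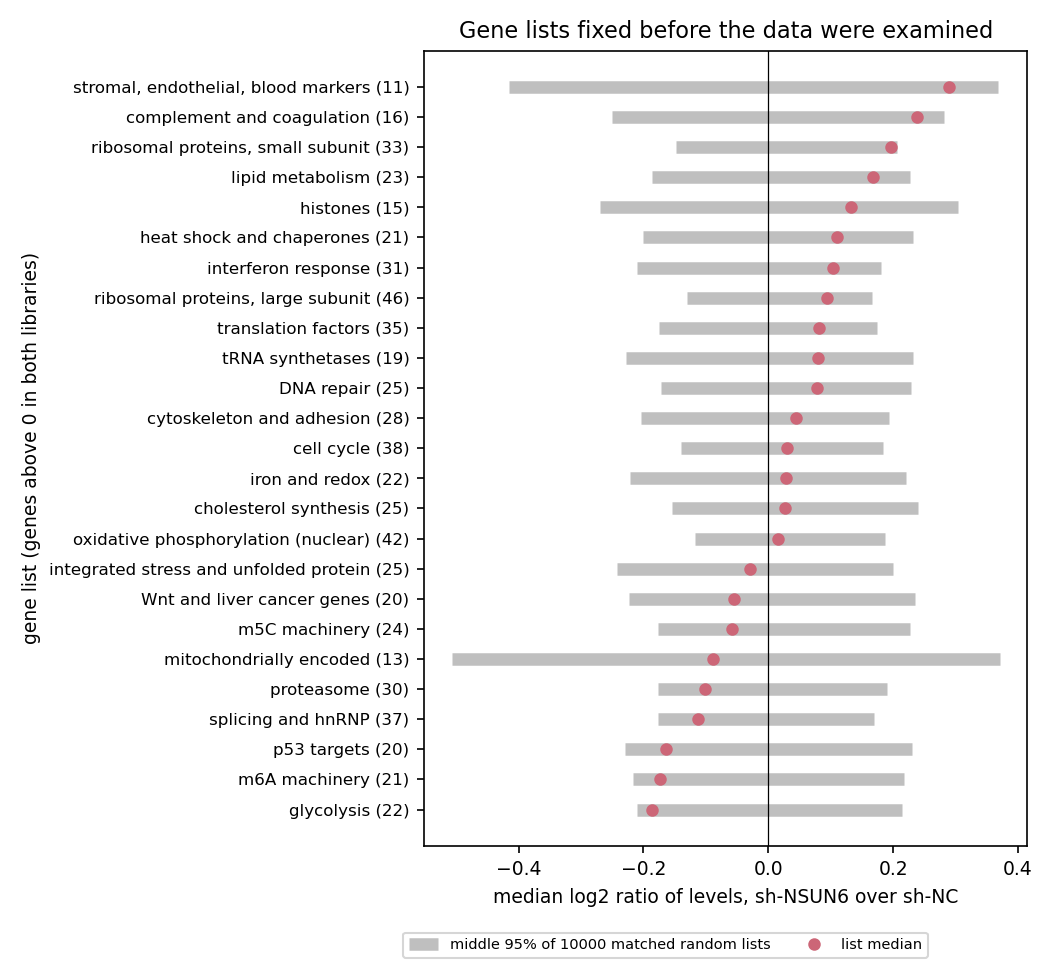
Median log2 ratio of gene-body levels, sh-NSUN6 over sh-NC (horizontal axis), for 25 gene lists (vertical axis, number of genes above 0 in both libraries in brackets). Red points are list medians and grey bars span the middle 95% of 10000 random lists matched on level. All 25 medians lie within their bars, the highest for stromal, endothelial and blood markers (0.29) and the lowest for glycolysis (-0.19).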

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

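Levels outside the transcribed region had no part in the comparisons, and they are given here because more genes had one in sh-NSUN6 than in the control; the choice was made after the values were seen. A promoter level above 0 was found for 5718 genes in sh-NSUN6, or 35.3% of those listed, and for 4615 genes in sh-NC, or 29.8%. A downstream level above 0 was found for 3216 genes in sh-NSUN6, or 19.8%, and for 2403 genes in sh-NC, or 15.5%. Among genes with such a level in both libraries, the median promoter level was 2.84% in sh-NC and 2.93% in sh-NSUN6, and the median downstream level was 2.31% and 2.40%.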

How the results depend on the processing

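Alternatives in other regions or contexts, and those limited to genes under 20%, were chosen after the results were seen. The counts of 2-fold genes, 691 higher and 630 lower, became 1745 and 1594 at 1.5-fold and 134 and 124 at 4-fold. They became 1357 and 1201 in 3' UTRs, and 167 and 176 when all 3 contexts had to differ 2-fold the same way. Taking the outer 5% of differences gave 343 on each side, a split fixed by construction. With the pseudocount they were 705 and 383, where genes above 0 in sh-NSUN6 alone enter on the higher side; the other causes were not tested. Exons, the CHH context, centring, a minimum level and genes under 20% alone kept each count within 1.5-fold. The mean of gene levels was 4.68% in sh-NC and 4.57% in sh-NSUN6, the opposite order to the medians; a mean by construction gives high genes more weight than the median does. The median log2 ratio was -0.027 at genes at or above the median mean level, a reversal of a value near 0, and the cause was not tested. Under its other alternatives it lay between 0.0037 and 0.041. Centring left the NSUN6 log2 ratio at 0.18. No gene list was outside the range in the main comparison; 1 was outside it with the pseudocount (glycolysis), 1 with random lists not matched (small-subunit ribosomal proteins) and 1 by the mean of the list (stromal, endothelial and blood markers). For the 20 largest differences, the 17 values in exons or 3' UTRs are a stricter comparison but not an independent one. Of these, 11 kept their direction and a 2-fold size, and 5 fell short of 2-fold. The other 1 changed sign, TNFRSF11B in exons at 0.0068, with both levels near the top of the scale. For THY1 and NRIP3 the 3' UTR ratio equals the gene-body ratio (6.34 and -2.02), so their agreement was fixed in advance. The protocadherin genes, whose reads may be shared, count as separate values. Centring, the pseudocount and the CHH context left all 59 of their values at 2-fold or more, but they move such large differences little. Above the 25th percentile of nonzero levels, 10337 genes were listed in sh-NC and 10955 in sh-NSUN6.

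No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. Call minimums of 10, 30 and 100 and weighting by coverage were not run, since no coverage is given. Depth is unknown, so no level carries an interval.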

Other observations

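The tests of levels of 50% and 95% in both libraries, and those of depth and of other cells for the hepatocyte genes, were chosen after the results were seen; those of gene names, of the 20 largest differences, of the motif and of exons against 3' UTRs were chosen before.

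High levels in both libraries were found for 96 genes at 50% or more, 6 of them mitochondrial, and 36 of the 96 were at 95% or more in each. The genes are of many kinds, and those named here are examples chosen after their values were seen, with no enrichment test. The chemokine gene CXCL1 was at 99.9% in sh-NC and 99.8% in sh-NSUN6, the interleukin gene IL1B at 99.1% and 99.3%, the matrix protease gene MMP1 at 98.9% and 98.8%, the collagen gene COL6A3 at 94.3% and 93.8%, the neurofilament gene NEFM at 98.7% and 97.4%, and the homeobox gene EMX2 at 98.3% and 97.4%. Of the 96 genes 67, or 69.8%, were at 50% or more in CG, CHG and CHH alike. The same pair of levels as another gene of the group was found for 5 of them (5.21%), all at 100% in both libraries. Reads shared in full between near-identical genes therefore do not account for most of the group. Genes that share only part of their reads can have unequal pairs, so sharing in part was not tested.

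In the 13 mitochondrially encoded genes the CHH level was above the CG level in 13 of 13 in both libraries, with medians of 56.1% and 37.5% in sh-NC and 54.4% and 36.3% in sh-NSUN6. Over all genes the order was the opposite one.

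The pattern of genes at 50% or more in both libraries was weighed against 3 explanations. Chance from few reads per gene is argued against, since 96 of 129 genes at 50% or more in sh-NC, or 74.4%, were so in sh-NSUN6, which is 93.9 times the 0.793% of all genes listed in both. A high level limited to some sequence contexts is argued against for the genes at 95% or more in both libraries. Of these, 97.2% were at 90% or more in every context with a level above 0. Picking genes by the level of all cytosines nearly fixes that share, so it does not speak to the other genes. For the other genes at 50% or more, methylation limited to some sequence contexts stays open. Unconverted RNA from stromal or blood cells may contribute, and it stays open: 36.4% of the listed markers of such cells were at 20% or more in both libraries, against 1.26% of all genes, among them COL1A1 at 36.1% and 20.8% and DCN at 24.1% and 31.6%, yet COL3A1 was at 2.69% and 2.26%, LUM at 4.39% and 7.65% and PDGFRB at 3.10% and 3.36%. Without abundance it cannot be told apart from methylation, as transcripts that the studied cells also make would dilute such RNA, and the knockdown is no candidate because the pattern is in both libraries.

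Genes for hepatocyte products were rarely listed in tables labelled HepG2, a line that secretes many of them. Of 35 such genes 26 were not listed in the tables used here, among them ALB, AFP, APOA1, APOB, TTR and SERPINA1, the first of which encodes albumin. Older gene names are argued against as the cause, since they found 0% of the 26. A low depth over all genes is argued against too. The median share listed was 100% in the 23 lists that describe neither liver products nor cells of other tissues. The complement and coagulation list was listed at 57.6%, and the stromal, endothelial and blood markers at 55%. Without coverage, a depth too low for weakly expressed genes stays open. Cells other than the labelled line, or a line that lost its hepatocyte programme, may account for the unlisted genes, and these cannot be told apart, because 11.4% of the list was above 0 in both libraries and no abundance or genotype was used. A selection of genes made before the tables used here was not tested and stays open.

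For the 20 largest differences, levels that rest on few covered regions are a candidate explanation: the share with a level in at most 2 of 4 regions was 4.51 times that of all genes. Loss or gain of methylation at specific sites cannot be told apart from other causes, since 11 of the 14 genes with levels in 3 contexts, or 78.6%, differed by 2-fold the same way in all 3, short of the 80% set as the limit. Picking these genes by the level of all cytosines also raises that share. An effect of the NSUN6 knockdown stays open and untested, as 1 library per group cannot separate it from differences between libraries.

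NSUN6 is known to methylate mRNAs within a CTCCA motif, often in 3' UTRs, so a lower 3' UTR level in sh-NSUN6 was looked for at genes with that motif. Of 9829 genes with a CHH level in both libraries and a 3' UTR in the annotation, 7507 had the motif and 2322 did not. The median log2 ratio differed by -0.017 after matching on 3' UTR length, at the 28.5th percentile of 2000 shuffles. The middle range of the shuffles ran from -0.058 to 0.064, so no lower level was found at the scale of whole 3' UTRs. Such a level combines all CHH cytosines of the region, so a loss at single motif sites could go unseen and is not excluded.

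A change along the whole transcript would appear in exons and 3' UTRs alike. Among 513 genes with a 2-fold difference over the gene body, 379, or 73.9%, had the same direction in exons and 3' UTRs, against 52.8% of 10296 genes. Selection on the gene body, which contains both regions, raises the first share, so a change along the whole gene could not be told apart from chance in either region.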
